A study of Mus musculus with 9 samples.

How the data were processed

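Gene expression was measured by RNA sequencing in 9 libraries of mouse kidney cortex, 3 from each of 3 groups, on day 4. Per the labels, the libraries were made from total RNA and sequenced on a DNBSEQ instrument. The authors deposited a table of 58075 RefSeq transcripts with Entrez gene numbers. Per the file headers its read count columns hold counts per transcript, and per the submitters' processing notes these come from RSEM 1.3.1, so that the deposited values are expected counts, with DESeq2 1.4.5 named beside it. The notes name GRCh38, a human build, for these mouse samples. The aligner and the mouse build are not given in the sources used here, and no genome positions are printed for that reason. The second set of deposited columns was read as FPKM from the values, since the transcript length that they imply was 1.01 to 1.02 times the annotated length minus 200 bases and the columns did not share 1 sum as TPM columns would. The authors' averages over groups were not used here.

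Expected counts were summed over the transcripts of each Entrez gene and rounded to whole numbers, which gave 17963 genes. Before rounding, 16.5% to 19.3% of the gene counts in a library lay more than 0.005 from a whole number. Symbols were taken from the RefSeq table of GRCm38.p6 for 17847 genes, and 116 gene numbers had none and stayed in the tests under their number. The table holds no mitochondrially encoded gene and no Xist. RSEM divides reads between similar transcripts, so values of close paralogs, such as the haemoglobin, Saa, metallothionein, Cyp4a and Slc22a genes, are less certain than their errors say. Library totals lay between 15029274 and 16690471 expected counts. At that depth a count of 3 over the 3 libraries of a group, the floor used for genes at 0, corresponds to 0.0576 to 0.0705 CPM.

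All 9 libraries were fitted together in edgeR 4.0.16 under R 4.3.3, with filterByExpr by group, TMM factors (0.855 to 1.105), a quasi-likelihood fit with group as the only term, and a test for each pair of groups. The filter removed 4009 genes and left 13954, and the common biological coefficient of variation was 0.234. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes of a comparison, and counts with a change of at least 2-fold follow the threshold of the study's design text. Log2 fold changes are given with the standard error of the fit after the plus-minus sign, and CPM values with the SD over 3 libraries. Tests were two-sided unless stated. A fold against a group at 0 counts is a lower bound against 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% exact counting interval.

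Gene lists for pathways and cell types of the kidney were written before the data were examined, as were the comparisons, the tests, the alternatives and the rule for the genes named. In each comparison 44 lists had at least 5 tested genes. They were tested with camera (limma 3.58.1) at its preset correlation of 0.01 and again with an estimated correlation, and with fry, which tests whether genes of a list move on balance in one direction and does not compare them with other genes. Adjusted p-values of lists are over the 44 lists of a comparison. Camera called 24 lists in cisplatin against control, 26 in YSJZD against cisplatin and 23 in YSJZD against control. With an estimated correlation none, none and 1 of these passed, the last being TNF signalling. Lists with fewer than 5 tested genes, such as erythroid, B cell, dendritic and hepatocyte markers, were not tested as lists.

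The genes named for each comparison are the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 10 CPM in a group and no overlap between the libraries of the groups, up to 4 members of each described list by smallest p, and genes from a fixed set of injury, TNF signalling, cell death, oxidative stress and transport that are given whatever their result. The fit was tested on simulated counts in which 13388 to 13396 genes passed the filter and 66 or 67 genes had a known change of each size. A change of 1.5-fold was called in 13.4%, 9.0% and 17.9% of genes in the order of the comparisons above, a change of 2-fold in 59.7%, 76.1% and 65.7%, and a change of 4-fold in 100%, 100% and 98.5%, with 8 to 10 unchanged genes called. The changed genes had a mean of at least 10 CPM in control. Only 129 to 134 genes were called per simulation, against 2694 to 7616 in the data, which makes the adjusted threshold stricter. These rates are therefore not the sensitivity of the real comparisons. A simulated list of 30 genes raised 1.5-fold was called by camera with either correlation and by fry, and of 43 unchanged lists fry also called 1 in YSJZD against control.

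Alternatives were DESeq2 size factors in edgeR, library totals without a composition factor, no filter, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of the 6 libraries compared, the replicate number as a block, and leaving out each library. For these last fits brackets hold the log2 fold change where a fold moved and the adjusted p where a call was lost, the highest of several. A limma fit on log2(FPKM + 1) and the reading of the fit without cisplatin replicate 3 as the one without a doubted library were added after the data were seen. Comparisons that share libraries were set against 15 simulated data sets per scenario. Gene spans came from GENCODE M21, which matched 97.8% of the tested genes, and sets of genes were compared with 10000 random sets in which each gene was drawn from the 100 nearest tested genes by the matched measures. The draws take genes as independent units, so their permutation p-values and ranges do not measure the spread between samples. Those draws, the tables and the figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.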

Results

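RNA was sequenced from samples of kidney cortex taken on day 4 from mice in 3 groups of 3 libraries each. The control group had received saline into the peritoneum and water by mouth. The cisplatin group had received cisplatin, a platinum drug against cancer that injures the kidney tubule, with water by mouth. The YSJZD group had received cisplatin with Yishen Jiangzhuo decoction, a herbal medicine, by mouth. The library totals were 16086212, 15033546 and 15775233 expected counts in the control group, 16690471, 16000324 and 16180486 in the cisplatin group, and 16657193, 15029274 and 15883380 in the YSJZD group. After filtering, 13954 genes were tested. The sources used here do not say that each of the 3 samples of a group came from its own mouse, and p-values measure the spread between these samples.

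Groups separated along the first principal component of log2 CPM (counts scaled to TMM-adjusted library totals), with 68.7% of variance. Control libraries lay from -89.7 to -77.3, YSJZD libraries from -21.9 to 4.55, and cisplatin libraries from 88.7 to 95.7. The second component held 11.6%, with YSJZD libraries from -48.2 to -34.8, control libraries from 16.4 to 29.5, cisplatin replicates 1 and 2 at 27.4 and 27.1 and cisplatin replicate 3 at -5.15. That library also stood apart on the third component, which held 5.4%, at 48.8 against 5.59 or less in every other library. In cisplatin replicate 3 the endothelial genes had a median log2 difference from the control mean of -0.92, against 0.07 and 0.01 in cisplatin replicates 1 and 2. The extracellular matrix genes stood at 0.48 in that library against 1.68 and 2.08, and the macrophage genes at 1.31 against 2.17 and 3.55, while the neutrophil genes were highest there, at 6.12 against 3.77 and 5.74.

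**Figure D1:**
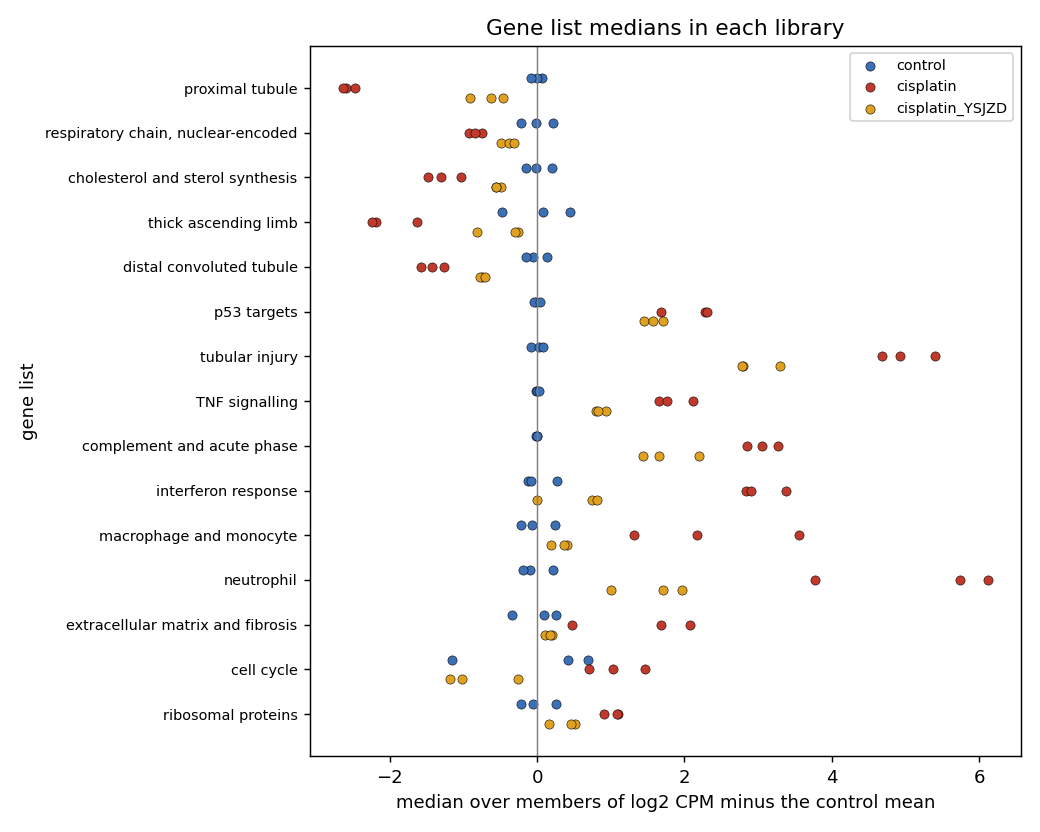
For each gene list on the vertical axis, points show 1 library each and give the median over the members of log2 CPM minus the control mean. Proximal tubule medians lay from -2.64 to -2.47 in cisplatin libraries and from -0.92 to -0.46 in YSJZD libraries, and p53 target medians lay from 1.68 to 2.31 and from 1.46 to 1.71.

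The comparison of cisplatin with control asks what the drug changed in the cortex by day 4. Transporters of the proximal tubule were far lower with cisplatin. Slc34a1 (Entrez gene 20505), the sodium phosphate cotransporter of the brush border, stood at 218 ± 95.5 CPM (SD, n = 3) against 7726 ± 1321 in control, a log2 fold change of -5.15 ± 0.50 (SE). Markers of tubular injury were far higher. Havcr1 (Entrez gene 171283), which encodes the injury marker KIM-1, stood at 1090 ± 158 CPM against 3.42 ± 1.25, a log2 fold change of 8.32 ± 0.63. Lcn2 (Entrez gene 16819), which encodes the iron-scavenging protein NGAL, stood at 2207 ± 1338 CPM against 3.29 ± 2.07 (9.38 ± 0.75). Cdkn1a (Entrez gene 12575), the p53 target that encodes the cell cycle inhibitor p21, stood at 772 ± 153 CPM against 6.51 ± 0.909 (6.89 ± 0.33). Lcn2 (9.996) moved over 1.5-fold without control replicate 3, as did Lcn2 (8.79) without cisplatin replicate 3.

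Among the genes with the greatest rise was Krt20, a keratin, at 676 ± 498 CPM against 0.121 ± 0.111 (12.39 ± 0.91). Several had 0 counts in all control libraries, so their rise is a lower bound against a floor of 3 counts over the group. The AP-1 subunit Fosl1 was higher at least 723-fold, the acute-phase gene Saa3 at least 263-fold, and Fgb, the fibrinogen beta chain, at least 238-fold. Trem1, a receptor of neutrophils and monocytes, was higher at least 176-fold and the membrane protein gene Ms4a8a at least 172-fold. With 1 count in control, the arginase gene Arg1 had a ratio of 2213 with a 95% counting interval of 397 to 87400, and the acute-phase gene Saa1 had a ratio of 2097 with a 95% counting interval of 376 to 82900. These intervals and floors cover counting error only. The greatest falls were in transporter and brush border genes, namely the organic anion transporter family members Slc22a28 (-8.85 ± 0.61), Slc22a22 (-8.45 ± 0.86) and Slc22a30 (-8.06 ± 0.53), the amino acid transporter Slc7a13 (-8.37 ± 0.41) and the meprin protease Mep1b (-8.11 ± 0.55). The haemoglobin gene Hba-a1 (-8.43 ± 0.46), the serine protease Tmprss9 (-7.44 ± 0.52) and the collagen gene Col19a1 (-7.42 ± 0.69) completed the 8 greatest falls. Hba-a1, Saa1 and the Slc22a28 and Slc22a30 pair have close paralogs, between which the authors' counting program divides reads. Krt20 (13.09) moved over 1.5-fold without control replicate 2, as did Krt20 (11.79) without control replicate 3 and Krt20 (11.60) and Mep1b (-8.81) without cisplatin replicate 3.

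**Figure D2:**
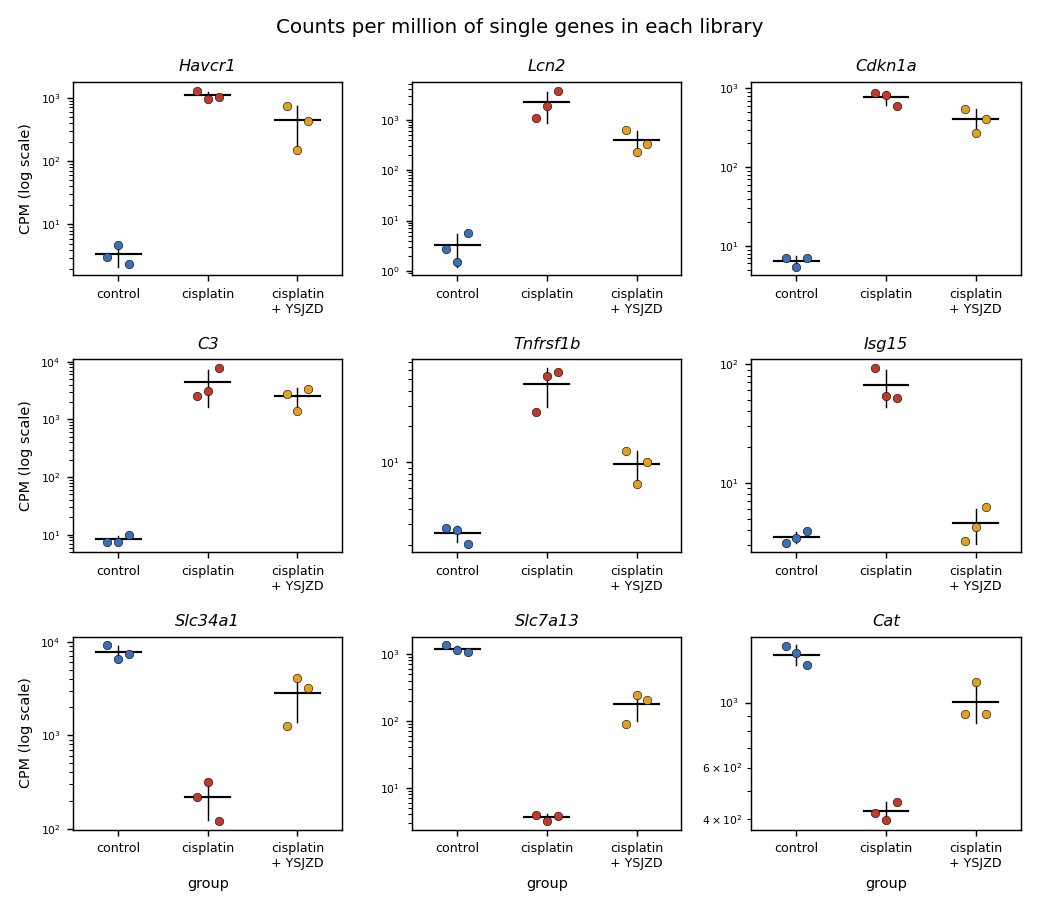
Points give the CPM of 9 genes in each library on a log scale, with the group mean as a horizontal bar and 1 SD to each side as a vertical line (n = 3). Havcr1 lay from 149.5 to 735.9 CPM in the YSJZD libraries and from 962 to 1267 in the cisplatin libraries, against 2.38 to 4.81 in control.

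Of the 13954 genes tested, 7616 (54.6%) passed at adjusted p under 0.05, 3987 higher and 3629 lower with cisplatin, and 4607 of them changed at least 2-fold (2596 higher, 2011 lower). Without cisplatin replicate 3 the count was 7409. Among the called genes 52.4% were higher, and with libraries scaled by their totals alone 66.1% of 7839 were, since the median of all genes was then 0.27 in place of 0.04 on the log2 scale. The lists called below kept the sign of their medians under that scaling.

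Of the 28 tubular injury genes tested, 28 rose and 0 fell (28 and 0 adjusted over the list alone), with camera adjusted p = 2.05e-14 (0.0783 with an estimated correlation, marked below as estimated). Examples were the intermediate filament gene Vim (3.30 ± 0.19), osteopontin Spp1 (5.99 ± 0.37), the tight junction gene Cldn4 (5.12 ± 0.35) and the protease inhibitor Timp1 (8.46 ± 0.61). Of the 40 p53 target genes tested, 34 rose and 3 fell (35 and 3 in the list alone), with camera adjusted p = 7.67e-11 (0.0783 estimated). They included Mdm2 (2.40 ± 0.14), which restrains p53, the cell death gene Pmaip1 (3.25 ± 0.18) and the growth arrest gene Btg2 (5.5 ± 0.31). Of the 12 genes of the secretory profile of senescent cells tested, 11 rose and 0 fell (11 and 0 in the list alone), with camera adjusted p = 2.55e-05 (0.0783 estimated). The list median was 5.18, and 4.48 with genes at 0 counts held at their bound, and members included the growth factor Gdf15 (5.59 ± 0.41) and the urokinase receptor Plaur (4.77 ± 0.45). Of the 20 immediate early genes tested, 19 rose and 0 fell (19 and 0 in the list alone), with camera adjusted p = 7.67e-11 (0.0783 estimated). Among them were the transcription factor genes Junb (3.73 ± 0.16), Egr1 (5.68 ± 0.27) and Maff (4.68 ± 0.27). Timp1 (9.15) moved over 1.5-fold without control replicate 2.

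Of the 78 genes of TNF signalling tested, 52 rose and 3 fell (55 and 4 in the list alone), with camera adjusted p = 9.62e-11 (0.0601 estimated). Members that rose included Junb, the membrane protease Mmp14 (3.5 ± 0.20), the cytokine signal inhibitor Socs3 (5.92 ± 0.36) and the necroptosis effector Mlkl (4.69 ± 0.28). Tnf itself was low, with 3 counts in control and 1.89 ± 1.43 CPM with cisplatin, a ratio of 25.9 with a 95% counting interval of 8.59 to 128. Both TNF receptor genes rose, Tnfrsf1a by 1.90 ± 0.19 and Tnfrsf1b by 4.18 ± 0.35 on the log2 scale, as did the NF-kB subunit genes Nfkb1 (1.53 ± 0.23) and Rela (2.01 ± 0.26). Of the 29 inflammatory cytokine and chemokine genes tested, 23 rose and 1 fell (23 and 1 in the list alone), with camera adjusted p = 4.61e-08 (0.0783 estimated). The list median was 4.21, and 4.12 with genes at 0 counts held at their bound. The chemokine genes Cxcl1 (8.10 ± 0.78), Ccl2 (5.71 ± 0.76) and Cxcl16 (2.19 ± 0.23), the cytokine gene Lif (5.90 ± 0.36) and Il1b (3.46 ± 0.62) rose, and Cxcl3 was higher at least 150.2-fold. The adhesion gene Icam1 rose as well (2.74 ± 0.19). Il6 was removed by the filter, with 39 counts over the cisplatin libraries and 1 over the control libraries, a ratio of 31.9 with a 95% counting interval of 5.4 to 1290. Cxcl1 (7.35) moved over 1.5-fold without cisplatin replicate 3, as did Ccl2 (6.97) without control replicate 3.

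Of the 39 apoptosis genes tested, 22 rose and 6 fell (22 and 6 in the list alone), with camera adjusted p = 0.00318 (0.0809 estimated). The death receptor gene Tnfrsf10b (3.55 ± 0.32), Casp8 (1.22 ± 0.11), Bak1 (1.96 ± 0.18) and Bax (1.56 ± 0.19) rose, and the survival gene Bcl2 did not pass (-0.39 ± 0.21, adjusted p = 0.142). Of the 16 pyroptosis and necroptosis genes tested, 12 rose and 0 fell (13 and 0 in the list alone), with camera adjusted p = 0.000143 (0.0783 estimated). They included the kinase gene Ripk3 (4.67 ± 0.37), Txnip (3.14 ± 0.28) and the pore protein gene Gsdmd (2.55 ± 0.30).

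Of the 32 targets of the oxidative stress regulator NRF2 tested, 16 rose and 6 fell (16 and 7 in the list alone), with camera adjusted p = 0.0345 (0.66 estimated). The list missed the threshold without control replicate 2 (0.0521), cisplatin replicate 1 (0.0647) or cisplatin replicate 3 (0.0502). The glutathione transferase Gsta2 (3.40 ± 0.36), the exporter Abcc3 (4.12 ± 0.50), the receptor kinase Epha2 (3.54 ± 0.25), the haem oxygenase Hmox1 (1.83 ± 0.30) and the quinone reductase Nqo1 (1.34 ± 0.24) rose, and the malic enzyme Me1 fell (-2.02 ± 0.16). Among 29 antioxidant enzyme genes, which did not pass as a list, 6 rose and 13 fell (6 and 14 in the list alone, camera adjusted p = 0.182). Catalase Cat stood at 426 ± 31.1 CPM against 1457 ± 109.7 (-1.77 ± 0.16), and the superoxide dismutases Sod1 (-1.53 ± 0.18) and Sod2 (-1.05 ± 0.20) and the selenium carrier Selenop (-2.25 ± 0.22) fell. Selenow (2.02 ± 0.21) and the paraoxonase Pon2 (1.28 ± 0.14) rose, and Gpx4 did not pass (-0.35 ± 0.15, adjusted p = 0.0717) but was called in DESeq2 (0.034). Of 18 genes of cisplatin transport and metal binding, 4 rose and 9 fell (5 and 9 in the list alone, camera adjusted p = 0.191). The metallothioneins Mt2 (7.02 ± 0.25) and Mt1 (5.68 ± 0.27) rose, while the cation transporter Slc22a2 (-2.68 ± 0.23) and the copper transporter Slc31a1 (-1.34 ± 0.15), both carriers of cisplatin, fell.

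Of the 27 complement and acute-phase genes tested, 25 rose and 0 fell (26 and 0 in the list alone), with camera adjusted p = 3.12e-09 (0.0783 estimated). The list median was 4.01 with or without genes at 0 counts held at their bound, and the complement component C3 rose from 8.34 ± 1.33 to 4470 ± 2819 CPM. The protease inhibitor gene Serpina3n (10.34 ± 0.57) and the lipopolysaccharide binding protein gene Lbp (2.72 ± 0.22) rose too. Of the 38 interferon response genes tested, 35 rose and 0 fell (36 and 0 in the list alone), with camera adjusted p = 1.70e-12 (0.198 estimated). Examples were the peptide transporter Tap1 (3.59 ± 0.18), the antiviral Bst2 (3.21 ± 0.20) and the regulators Irf7 (3.69 ± 0.24) and Irf9 (2.01 ± 0.11). Of the 10 class II antigen presentation genes tested, 6 rose and 0 fell (6 and 1 in the list alone), with camera adjusted p = 0.0189 (0.346 estimated). The class II loading genes H2-DMb1 (2.05 ± 0.21) and H2-DMa (1.82 ± 0.18) and the protease Ctss (4.16 ± 0.59) rose. Of the 20 macrophage and monocyte markers tested, 14 rose and 0 fell (17 and 0 in the list alone), with camera adjusted p = 0.000169 (0.421 estimated). They included Cd68 (4.74 ± 0.34), Itgam (6.68 ± 0.64) and Cd14 (6.42 ± 0.63). Of the 11 neutrophil markers tested, 11 rose and 0 fell (11 and 0 in the list alone), with camera adjusted p = 6.75e-06 (0.299 estimated). They included S100a8 (6.36 ± 0.63) and Lcn2, which injured tubule cells also make. Il1r2 had a ratio of 938 with a 95% counting interval of 168 to 37100 and S100a9 had a ratio of 244 with a 95% counting interval of 67.3 to 2020. Among the cisplatin libraries the macrophage markers were lowest and the neutrophil markers highest in cisplatin replicate 3. Ctss (3.15) and Itgam (5.96) moved over 1.5-fold without cisplatin replicate 2, as did Cd14 (5.53) without cisplatin replicate 3.

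Of the 62 proximal tubule genes tested, 3 rose and 49 fell (4 and 51 in the list alone), with camera adjusted p = 2.05e-14 (0.0783 estimated). The median fall was -2.60 on the log2 scale, and examples were the transporters Slc6a20b (-4.29 ± 0.22) and Slc22a18 (-3.09 ± 0.19) and the glutathione-cleaving enzyme Ggt1 (-2.88 ± 0.18). Of the 13 markers of the thick ascending limb tested, 0 rose and 10 fell (0 and 10 in the list alone), with camera adjusted p = 0.000618 (0.346 estimated). The growth factor Egf (-5.30 ± 0.49), the junction gene Cldn10 (-2.68 ± 0.18), the chloride channel subunit Bsnd (-3.06 ± 0.33) and uromodulin Umod (-1.88 ± 0.41) fell. Of the 12 markers of the distal convoluted tubule tested, 0 rose and 10 fell (0 and 10 in the list alone), with camera adjusted p = 0.000305 (0.12 estimated). They included the sodium chloride cotransporter Slc12a3 (-4.74 ± 0.50) and the calcium binding protein Pvalb (-7.37 ± 0.44). Podocyte markers did not pass as a list, since 3 rose and 2 fell of 11 tested (3 and 2 in the list alone, camera adjusted p = 0.709). Slc12a3 (-5.60) moved over 1.5-fold without cisplatin replicate 3.

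Of the 49 nuclear genes of the respiratory chain tested, 0 rose and 40 fell (0 and 43 in the list alone), with camera adjusted p = 7.67e-11 (0.41 estimated). They included Sdha (-1.75 ± 0.16), Ndufs1 (-2.06 ± 0.21) and Ndufa10 (-1.23 ± 0.11). Of the 22 genes of cholesterol and sterol synthesis tested, 0 rose and 16 fell (0 and 16 in the list alone), with camera adjusted p = 1.94e-05 (0.128 estimated). The enzymes Cyp51 (-4.65 ± 0.27), Mvd (-3.13 ± 0.19) and Hmgcs1 (-3.07 ± 0.28) fell. Of the 8 gluconeogenesis genes tested, 0 rose and 4 fell (0 and 5 in the list alone), with camera adjusted p = 0.00912 (0.456 estimated). Pyruvate carboxylase Pcx (-2.10 ± 0.13) and the phosphatase Fbp1 (-2.16 ± 0.29) fell. Of the genes of fatty acid oxidation and PPARA, 14 rose and 24 fell of 51 tested (14 and 24 in the list alone, camera adjusted p = 0.235), and the list mean (0.14) and median (-0.15) differed in sign. Its members Cyp4a14 (6.23 ± 0.44) and Angptl4 (3.47 ± 0.20) rose, and Bdh1, a ketone enzyme, fell (-4.12 ± 0.27).

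Of the 44 cell cycle genes tested, 16 rose and 0 fell (8 and 0 in the list alone), with camera adjusted p = 0.00188 (0.708 estimated). The number that rose was 10 without control replicate 1, 9 without control replicate 3 and 7 without cisplatin replicate 1. Control replicate 1 had a list median of -1.15 against 0.69 and 0.43 in the other control libraries, and members that rose included Cdk2 (1.27 ± 0.17), Mcm7 (0.82 ± 0.19) and Ube2c (2.17 ± 0.56). Of the 33 extracellular matrix genes tested, 25 rose and 0 fell (25 and 0 in the list alone), with camera adjusted p = 4.16e-06 (0.41 estimated). The collagen crosslinking enzyme Lox (5.71 ± 0.41) and the collagen Col18a1 (2.78 ± 0.29) rose. Of the 82 ribosomal protein genes tested, 73 rose and 0 fell (74 and 1 in the list alone), with camera adjusted p = 8.40e-14 (0.41 estimated). Their share of counts was 3.53% to 4.38% in cisplatin libraries and 1.52% to 1.89% in control, with Rps12 at 1.73 ± 0.17 and Rpl30 at 1.27 ± 0.13. Of the 15 glucocorticoid response genes tested, 10 rose and 1 fell (10 and 1 in the list alone), with camera adjusted p = 0.000184 (0.0783 estimated). Besides both metallothioneins they included the kinase gene Pdk4 (6.38 ± 0.48) and the transcription factor gene Zbtb16 (4.29 ± 0.28).

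The other 16 lists did not pass, with camera adjusted p from 0.0549 to 0.903. The numbers that rose and fell, with those in the list alone in brackets, were 11 and 6 of 27 ferroptosis and iron genes (11 and 6), 7 and 4 of 13 oxidant-producing enzymes (7 and 4), 14 and 14 of 32 unfolded protein response genes (14 and 15), 4 and 11 of 18 heat shock genes (4 and 12), 6 and 5 of 20 circadian clock genes (6 and 5) and 6 and 6 of 20 hypoxia genes (6 and 6). They were 4 and 6 of 16 glycolysis genes (4 and 6), 1 and 6 of 13 fatty acid synthesis genes (1 and 6), 9 and 3 of 12 targets of the receptors AhR, CAR and PXR (9 and 3), 1 and 5 of 10 sex-linked and sex-biased genes (1 and 5), 0 and 5 of 11 principal cell markers (0 and 5) and 2 and 6 of 12 intercalated cell markers (3 and 6). The remaining numbers were 4 and 4 of 13 thin limb markers (5 and 4), 1 and 4 of 14 endothelial markers (0 and 2), 8 and 1 of 15 mesangial and fibroblast markers (8 and 1) and 2 and 1 of 5 T and NK cell markers (2 and 1). Among the sex-biased genes, Kap, an androgen-driven transcript of the proximal tubule, fell from 53190 ± 9720 to 3913 ± 1654 CPM, and Cyp2e1 fell by 5.0 ± 0.35 on the log2 scale. The median, mean and test direction differed in sign for the unfolded protein, glycolysis and thin limb lists, as for fatty acid oxidation.

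The comparison of YSJZD with cisplatin asks what the decoction changed in mice that had received the drug. Proximal tubule transporters were higher with YSJZD. Slc34a1 stood at 2857 ± 1460 CPM (SD, n = 3) against 218 ± 95.5 with cisplatin alone, a log2 fold change of 3.71 ± 0.47, and Slc7a13 at 179.9 ± 79.4 against 3.61 ± 0.361 (5.64 ± 0.37). Of 29 cytokine and chemokine genes 17 fell and 2 rose. The TNF receptor gene Tnfrsf1b stood at 9.62 ± 2.89 CPM against 45.5 ± 16.4 (-2.24 ± 0.31). Lcn2 stood at 390.2 ± 202 CPM against 2207 ± 1338 (-2.5 ± 0.54, adjusted p = 0.0058). Havcr1 stood at 437 ± 293 against 1090 ± 158 (-1.32 ± 0.45, adjusted p = 0.0444), and its call was lost in 8 of 9 fits that left out 1 library (adjusted p from 0.0527 to 0.115) and in the fit of these 6 libraries alone (0.0796). Without YSJZD replicate 1 the call was kept (0.00952) and Havcr1 (-1.92) moved over 1.5-fold.

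The greatest rises were in transporter genes of the proximal tubule, Slc22a22 (6.49 ± 0.83), Slc22a28 (5.89 ± 0.57), Slc22a30 (5.5 ± 0.49), Slc22a26 (5.32 ± 0.57) and Slc22a8 (5.08 ± 0.71) and Slc7a13, with the protease Mep1b (6.33 ± 0.53) and the sugar-conjugating enzyme gene Ugt3a1 (5.02 ± 0.43). The greatest falls were in genes of myeloid cells, namely Arg1 (-7.47 ± 0.73), the chemokine Cxcl3 (-6.58 ± 0.50), the lectin Clec4d (-6.15 ± 0.77), the decoy receptor Il1r2 (-5.89 ± 0.62), the chitinase-like Chil3 (-5.74 ± 0.65) and the collagenase Mmp8 (-5.52 ± 0.77), and in the protease inhibitor Slpi (-5.68 ± 0.78). Hmga1b, which resembles the chromatin gene Hmga1, was also among them (-7.38 ± 1.73), with 239.2 CPM in cisplatin replicate 1 and 4.11 and 4.35 in the other cisplatin libraries. Without that library its log2 fold change was -3.10, limma-voom (adjusted p = 0.206) and limma on log2(FPKM + 1) (0.0528) did not call it, and DESeq2 gave it no adjusted p. In all, 4942 of 13954 genes passed (35.4%), 2426 higher and 2516 lower with YSJZD, and 2667 changed at least 2-fold (1084 higher, 1583 lower). Without cisplatin replicate 3 the count was 4814. Slc22a22 (5.79), Slc22a28 (5.30) and Slc22a8 (4.33) moved over 1.5-fold without YSJZD replicate 2, as did Slc22a26 (6.42) and Mep1b (7.04) without cisplatin replicate 3, Arg1 (-6.47), Clec4d (-5.20), Chil3 (-4.73) and Mmp8 (-4.83) without cisplatin replicate 2, Clec4d (-6.76) and Il1r2 (-6.81) without YSJZD replicate 1, Slpi (-4.62) without cisplatin replicate 1 and Slpi (-6.64) without YSJZD replicate 3.

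Of the 28 tubular injury genes tested, 0 rose and 22 fell (0 and 23 in the list alone), with camera adjusted p = 2.69e-09 (0.18 estimated). Vim (-3.06 ± 0.19), Krt20 (-4.34 ± 0.56), Cldn4 (-2.44 ± 0.31) and the calcium binding protein S100a6 (-4.30 ± 0.43) fell. Of the 40 p53 target genes tested, 1 rose and 12 fell (1 and 12 in the list alone), with camera adjusted p = 0.00149 (0.353 estimated). Pmaip1 (-1.55 ± 0.16), Btg2 (-1.81 ± 0.26), the decoy receptor Tnfrsf23 (-2.79 ± 0.35) and Trp53inp1 (-1.63 ± 0.24) fell, and Cdkn1a fell by 0.91 ± 0.25 on the log2 scale. The number of p53 targets that fell was 19 without cisplatin replicate 3 and 7 without cisplatin replicate 2. Of the 20 immediate early genes tested, 0 rose and 18 fell (0 and 18 in the list alone), with camera adjusted p = 2.20e-09 (0.118 estimated). Klf4 (-1.99 ± 0.18), Ier2 (-1.51 ± 0.16) and Egr1 (-1.99 ± 0.22) fell. Of the 12 senescence secretory genes tested, 0 rose and 7 fell (0 and 7 in the list alone), with camera adjusted p = 0.00149 (0.18 estimated). Plaur (-3.05 ± 0.40) was among those that fell. Of the 15 glucocorticoid response genes tested, 0 rose and 9 fell (0 and 10 in the list alone), with camera adjusted p = 0.000393 (0.18 estimated). They included Mt2 (-2.75 ± 0.21) and Mt1 (-2.74 ± 0.23). Krt20 (-3.56) moved over 1.5-fold without cisplatin replicate 3. Cdkn1a lost its call in 4 of 9 leave-one-out fits (0.0601 without cisplatin replicate 1).

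Of the 78 genes of TNF signalling tested, 1 rose and 36 fell (2 and 36 in the list alone), with camera adjusted p = 1.83e-05 (0.118 estimated). They included Mmp14 (-2.02 ± 0.19), Junb (-1.48 ± 0.14) and Mlkl (-2.49 ± 0.24). Tnf fell to 0.507 ± 0.129 CPM (-1.87 ± 0.62, adjusted p = 0.0377), and Nfkb1 (-0.79 ± 0.23) and Rela (-1.01 ± 0.25) fell. Tnfrsf1a did not pass (-0.20 ± 0.18, adjusted p = 0.411). Of the 29 inflammatory cytokine and chemokine genes tested, 2 rose and 17 fell (2 and 17 in the list alone), with camera adjusted p = 7.51e-05 (0.18 estimated). The chemokines Ccl9 (-4.69 ± 0.72), Ccl6 (-4.51 ± 0.83) and Ccl2 (-2.01 ± 0.57), Il1b (-2.97 ± 0.59) and Tgfb1 (-1.46 ± 0.25) fell, and Cxcl1 (-0.97 ± 0.48, adjusted p = 0.138) and Icam1 (-0.24 ± 0.17, adjusted p = 0.306) did not pass. Cxcl1 depended on single libraries, with -1.38 and a call without cisplatin replicate 1 (adjusted p = 0.0144) and -0.225 without cisplatin replicate 3 (0.677). Il6 had 2 counts over the YSJZD libraries against 39, a ratio of 18.4 with a 95% counting interval of 4.77 to 158. Of the 27 complement and acute-phase genes tested, 1 rose and 16 fell (1 and 19 in the list alone), with camera adjusted p = 0.000124 (0.18 estimated). Serpina3n (-2.90 ± 0.35) and Lbp (-1.41 ± 0.20) fell, and C3 did not pass (-0.84 ± 0.42, adjusted p = 0.145), with -0.192 without cisplatin replicate 3 (0.669). Of the 38 interferon response genes tested, 0 rose and 33 fell (0 and 33 in the list alone), with camera adjusted p = 9.24e-16 (0.18 estimated). The antiviral genes Isg15 (-3.85 ± 0.30), Oas1a (-3.30 ± 0.22), Oasl2 (-3.72 ± 0.27) and Usp18 (-3.86 ± 0.28) fell, and Isg15 stood at 4.59 ± 1.51 CPM against 66.1 ± 22.8 with cisplatin and 3.49 ± 0.393 in control. Tnf (-1.05) moved over 1.5-fold without cisplatin replicate 3, as did Ccl9 (-3.54) and Ccl6 (-2.87) without cisplatin replicate 2 and Ccl2 (-2.89) without YSJZD replicate 3. Tnf lost its call in 5 of 9 leave-one-out fits (0.162 without cisplatin replicate 3), Nfkb1 lost its call without YSJZD replicate 2 (0.0821) or YSJZD replicate 3 (0.0689), Rela lost its call without YSJZD replicate 3 (0.0515) and Ccl2 lost its call without YSJZD replicate 1 (0.0637) or YSJZD replicate 2 (0.072).

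Of the 20 macrophage and monocyte markers tested, 0 rose and 14 fell (0 and 15 in the list alone), with camera adjusted p = 5.37e-06 (0.353 estimated). Cd68 (-2.93 ± 0.30), Itgam (-4.24 ± 0.54) and Fcgr1 (-3.53 ± 0.50) fell. Of the 11 neutrophil markers tested, 0 rose and 11 fell (0 and 11 in the list alone), with camera adjusted p = 6.99e-07 (0.245 estimated). S100a8 (-4.17 ± 0.52) and the chemokine receptor Cxcr2 (-2.73 ± 0.41) fell. Of the 39 apoptosis genes tested, 4 rose and 17 fell (5 and 19 in the list alone), with camera adjusted p = 0.0192 (0.182 estimated). Bak1 (-1.26 ± 0.18) fell, the mitochondrial genes Endog (1.12 ± 0.16) and Aifm1 (1.0 ± 0.17) rose, and Bax (-0.02 ± 0.18, adjusted p = 0.952) and Bcl2 (0.21 ± 0.21, adjusted p = 0.45) did not pass. Of the 16 pyroptosis and necroptosis genes tested, 1 rose and 11 fell (1 and 13 in the list alone), with camera adjusted p = 2.27e-05 (0.118 estimated). Ripk3 (-2.82 ± 0.32), the nucleic acid sensor Zbp1 (-3.43 ± 0.43) and the inflammasome gene Nlrp3 (-2.39 ± 0.38) fell. Itgam (-3.52) and Fcgr1 (-2.88) moved over 1.5-fold without cisplatin replicate 2.

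Of the 62 proximal tubule genes tested, 50 rose and 1 fell (52 and 1 in the list alone), with camera adjusted p = 1.22e-18 (0.118 estimated). The median rise was 1.80, and examples were Slc6a20b (3.09 ± 0.21), Slc22a12 (3.26 ± 0.26) and Slc3a1 (1.5 ± 0.12). Of the 13 markers of the thick ascending limb tested, 10 rose and 0 fell (12 and 0 in the list alone), with camera adjusted p = 4.82e-05 (0.245 estimated). Egf (3.73 ± 0.46) and Cldn10 (1.57 ± 0.18) rose, and Umod did not pass (1.04 ± 0.40, adjusted p = 0.0653) but was called without cisplatin replicate 3 (1.46, adjusted p = 0.0203) or YSJZD replicate 1 (0.0449), in DESeq2 (0.024) and with the replicate block (0.0352). Of the 12 markers of the distal convoluted tubule tested, 4 rose and 0 fell (4 and 0 in the list alone), with camera adjusted p = 0.005 (0.245 estimated). Leaving out cisplatin replicate 2 gave 7 that rose. Slc12a3 (3.15 ± 0.47) and Pvalb (2.93 ± 0.46) rose. Of the 12 intercalated cell markers tested, 6 rose and 1 fell (6 and 1 in the list alone), with camera adjusted p = 0.0125 (0.477 estimated). Their median stood at -1.82 in cisplatin replicate 1 against -0.33 and -0.60 in the other cisplatin libraries, and without that library the list did not pass (camera adjusted p = 0.1). The ammonia transporter Rhcg (2.48 ± 0.31) and the anion exchanger Slc4a1 (3.08 ± 0.39) rose. Slc12a3 (4.01) moved over 1.5-fold without cisplatin replicate 3.

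Of the 49 nuclear genes of the respiratory chain tested, 26 rose and 0 fell (31 and 0 in the list alone), with camera adjusted p = 1.03e-07 (0.477 estimated). The number that rose was 16 without cisplatin replicate 1, cisplatin replicate 3 or YSJZD replicate 3, and examples were Sdha (1.10 ± 0.16) and Ndufs1 (1.21 ± 0.21). Of the 51 genes of fatty acid oxidation and PPARA tested, 24 rose and 2 fell (26 and 2 in the list alone), with camera adjusted p = 5.37e-06 (0.353 estimated). They included Bdh1 (2.70 ± 0.25), Cyp4a10 (1.51 ± 0.21), Cpt2 (1.16 ± 0.13) and Hadh (1.09 ± 0.16). Of the 22 genes of cholesterol and sterol synthesis tested, 10 rose and 1 fell (11 and 1 in the list alone), with camera adjusted p = 0.000612 (0.245 estimated). They included Cyp51 (2.68 ± 0.25), Mvd (1.75 ± 0.18) and Sqle (1.27 ± 0.16). Of the 8 gluconeogenesis genes tested, 4 rose and 0 fell (5 and 0 in the list alone), with camera adjusted p = 0.0119 (0.482 estimated). Without cisplatin replicate 3 the list did not pass (0.0836). Those that rose included Pcx (1.38 ± 0.13) and Fbp1 (1.26 ± 0.28). Of the 18 genes of cisplatin transport and metal binding tested, 9 rose and 3 fell (9 and 4 in the list alone), with camera adjusted p = 0.0299 (0.245 estimated). This list did not pass without YSJZD replicate 1 (0.0614). Ggt1 (1.86 ± 0.17), Kyat3 (1.65 ± 0.12), Slc22a2 (1.81 ± 0.22) and Slc31a1 (0.68 ± 0.15) rose. Of the 10 sex-linked and sex-biased genes tested, 5 rose and 0 fell (6 and 0 in the list alone), with camera adjusted p = 0.00385 (0.4 estimated). They included Cyp2e1 (3.60 ± 0.33) and Kap (1.84 ± 0.41).

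Of the 44 cell cycle genes tested, 0 rose and 34 fell (0 and 38 in the list alone), with camera adjusted p = 3.44e-10 (0.415 estimated). Leaving out YSJZD replicate 2 gave 22 that fell. Hmgb2 (-1.36 ± 0.18), Aurkb (-3.13 ± 0.55) and Ube2c (-3.19 ± 0.59) fell. Of the 33 extracellular matrix genes tested, 0 rose and 22 fell (0 and 25 in the list alone), with camera adjusted p = 1.69e-07 (0.353 estimated). Lox (-3.93 ± 0.36), the proteoglycan Vcan (-3.79 ± 0.53) and the gelatinase Mmp2 (-2.44 ± 0.34) fell, a group that stood lower in cisplatin replicate 3 than in the other cisplatin libraries. Of the 82 ribosomal protein genes tested, 0 rose and 68 fell (0 and 72 in the list alone), with camera adjusted p = 2.15e-14 (0.411 estimated). Without YSJZD replicate 2 the number was 35. Those that fell included Rps12 (-1.19 ± 0.16) and Rps24 (-0.93 ± 0.16). Among antioxidant and NRF2 genes, Cat (1.23 ± 0.15), Sod1 (0.91 ± 0.18) and Gpx4 (0.49 ± 0.15) rose, and Sod2 (0.22 ± 0.20, adjusted p = 0.426), Hmox1 (-0.25 ± 0.29, adjusted p = 0.524) and Nqo1 (0.37 ± 0.23, adjusted p = 0.252) did not pass. Aurkb (-3.85) moved over 1.5-fold without YSJZD replicate 3. Gpx4 lost its call in 4 of 9 leave-one-out fits (0.0774 without YSJZD replicate 2).

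The 18 lists that did not pass had camera adjusted p from 0.0698 to 0.99. The numbers that rose and fell with YSJZD, with those in the list alone in brackets, were 6 and 6 of 27 ferroptosis and iron genes (6 and 7), 3 and 6 of 32 NRF2 targets (3 and 6), 8 and 6 of 29 antioxidant enzymes (9 and 6), 3 and 7 of 13 oxidant-producing enzymes (3 and 7), 9 and 6 of 32 unfolded protein response genes (11 and 9) and 4 and 4 of 18 heat shock genes (5 and 4). Further numbers were 1 and 3 of 10 class II antigen presentation genes (1 and 3), 1 and 3 of 20 circadian clock genes (1 and 3), 3 and 4 of 20 hypoxia genes (3 and 4), 4 and 3 of 16 glycolysis genes (4 and 4), 2 and 0 of 13 fatty acid synthesis genes (2 and 0) and 2 and 3 of 12 targets of the receptors AhR, CAR and PXR (2 and 3). The last were 3 and 0 of 11 principal cell markers (1 and 0), 3 and 3 of 13 thin limb markers (3 and 3), 1 and 2 of 11 podocyte markers (1 and 2), 0 and 3 of 14 endothelial markers (0 and 3), 0 and 5 of 15 mesangial and fibroblast markers (0 and 5) and 1 and 1 of 5 T and NK cell markers (1 and 1). The class II regulator gene Ciita rose (2.59 ± 0.34) although its list did not pass. The median, mean and test direction differed in sign for the unfolded protein, heat shock, glycolysis and T and NK cell lists.

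The comparison of YSJZD with control asks what still differed from healthy cortex in mice that had received both cisplatin and the decoction. Injury and p53 genes were far higher than in control. Havcr1 stood at 437 ± 293 CPM (SD, n = 3) against 3.42 ± 1.25, a log2 fold change of 7.0 ± 0.60, Lcn2 at 390.2 ± 202 against 3.29 ± 2.07 (6.88 ± 0.68), and Cdkn1a at 412 ± 142 against 6.51 ± 0.909 (5.98 ± 0.32). Slc34a1 stood at 2857 ± 1460 CPM against 7726 ± 1321 (-1.44 ± 0.43, adjusted p = 0.0421). Havcr1 (6.398) moved over 1.5-fold without YSJZD replicate 1, as did Lcn2 (7.5) without control replicate 3. Slc34a1 lost its call in 6 of 9 leave-one-out fits (0.122 without control replicate 1).

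The genes with the greatest rises were C3, at 2503 ± 985 CPM against 8.34 ± 1.33 (8.23 ± 0.58), Krt20 (8.06 ± 0.89), Serpina3n (7.44 ± 0.57), Cxcl1 (7.13 ± 0.78), Havcr1, Lcn2 and Cyp4a14, a PPARA target that oxidises fatty acids, at 1137 ± 418 CPM against 8.8 ± 2.15 (7.01 ± 0.46). Saa1 had a ratio of 714 with a 95% counting interval of 128 to 28200. The greatest falls were in Hba-a1 (-8.82 ± 0.48), the phosphodiesterase Pde6a (-5.05 ± 0.48), the methyltransferase Inmt (-4.99 ± 0.78), Pvalb (-4.45 ± 0.36), Eddm3b (-4.45 ± 0.51) and A2m (-4.39 ± 0.71). Each with 1 count in the YSJZD group, the very long gene Fhit had a ratio of 618 with a 95% counting interval of 110 to 24400 of control over YSJZD, and Cntnap5a had a ratio of 526 with a 95% counting interval of 94 to 20800. Of 13954 genes, 2694 (19.3%) passed, 1386 higher and 1308 lower with YSJZD, and 1402 changed at least 2-fold (851 higher, 551 lower). Among the called genes 51.4% were higher, and with libraries scaled by totals alone 75.4% of 3174 were, the median of all genes then being 0.20 in place of 0.01. Leaving out control replicate 1 or control replicate 2 lowered the count to 1607 and 1699, and leaving out cisplatin replicate 3 raised it to 3138. Krt20 (8.76) moved over 1.5-fold without control replicate 2, as did Krt20 (7.46) and A2m (-3.78) without control replicate 3 and Inmt (-6.47) and Eddm3b (-5.12) without YSJZD replicate 2.

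Of the 28 tubular injury genes tested, 25 rose and 0 fell (27 and 0 in the list alone), with camera adjusted p = 2.60e-19 (0.063 estimated). Spp1 (5.41 ± 0.36), Gdf15 (4.84 ± 0.40) and the fibrinogen chain Fga (4.63 ± 0.44) rose. Of the 40 p53 target genes tested, 31 rose and 1 fell (32 and 2 in the list alone), with camera adjusted p = 1.24e-17 (0.0526 estimated). The receptor gene Eda2r (6.27 ± 0.44), Phlda3 (4.89 ± 0.37) and Mdm2 (1.78 ± 0.14) rose. Of the 39 apoptosis genes tested, 12 rose and 2 fell (15 and 2 in the list alone), with camera adjusted p = 0.00137 (0.0774 estimated). The p53 target Bbc3 (3.63 ± 0.35), Pmaip1 (1.69 ± 0.17) and Bax (1.54 ± 0.19) rose, and Bcl2 (-0.17 ± 0.21, adjusted p = 0.617) did not pass. Of the 16 pyroptosis and necroptosis genes tested, 5 rose and 0 fell (6 and 1 in the list alone), with camera adjusted p = 0.0221 (0.251 estimated). They included Mlkl (2.20 ± 0.28) and Ripk3 (1.85 ± 0.37). Of the 12 senescence secretory genes tested, 6 rose and 0 fell (8 and 0 in the list alone), with camera adjusted p = 5.62e-05 (0.063 estimated). The list median was 2.52, and 2.02 with genes at 0 counts held at their bound. Of the 20 immediate early genes tested, 14 rose and 0 fell (17 and 0 in the list alone), with camera adjusted p = 4.15e-12 (0.0526 estimated). They included Egr1 (3.70 ± 0.25), Maff (3.54 ± 0.27) and Btg2 (3.68 ± 0.29). Of the 15 glucocorticoid response genes tested, 7 rose and 0 fell (9 and 1 in the list alone), with camera adjusted p = 0.000235 (0.0865 estimated). They included Mt2 (4.28 ± 0.23), Mt1 (2.94 ± 0.24) and Pdk4 (4.98 ± 0.45). Pdk4 (4.38) moved over 1.5-fold without YSJZD replicate 2.

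**Figure D3:**
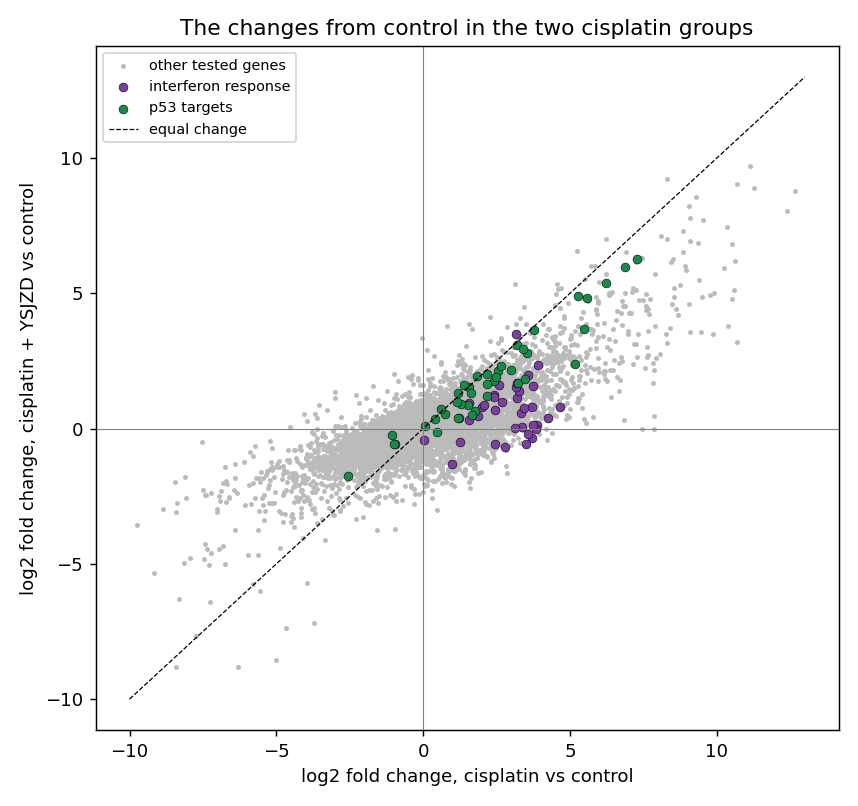
Each point is a tested gene, with the log2 fold change of cisplatin against control on the horizontal axis and that of YSJZD against control on the vertical axis, and the dashed line marks equal change. The p53 targets (green) had medians of 2.16 and 1.67 and the interferon response genes (purple) had medians of 3.16 and 0.64.

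Of the 78 genes of TNF signalling tested, 36 rose and 2 fell (47 and 3 in the list alone), with camera adjusted p = 6.77e-13 (0.033 estimated). Its median was 0.84, and 0.80 with genes at 0 counts held at their bound. Junb (2.26 ± 0.15), Icam1 (2.5 ± 0.19), the NF-kB regulator Bcl3 (2.20 ± 0.18), Tnfrsf1a (1.69 ± 0.19), Tnfrsf1b (1.94 ± 0.34) and Rela (1.00 ± 0.25) rose, and Nfkb1 passed narrowly (0.73 ± 0.23, adjusted p = 0.0499). Tnf did not pass (adjusted p = 0.0612), with a ratio of 7.21 with a 95% counting interval of 2.2 to 37.3. Of the 29 inflammatory cytokine and chemokine genes tested, 15 rose and 0 fell (18 and 0 in the list alone), with camera adjusted p = 1.16e-07 (0.063 estimated). The list median was 2.05, and 1.75 with genes at 0 counts held at their bound. Lif (4.86 ± 0.36), Ccl2 (3.70 ± 0.77) and Cxcl16 (1.89 ± 0.23) rose, Ccl20 had a ratio of 48.4 with a 95% counting interval of 8.34 to 1950, and Il1b did not pass (0.49 ± 0.67, adjusted p = 0.662). Of the 27 complement and acute-phase genes tested, 16 rose and 0 fell (18 and 0 in the list alone), with camera adjusted p = 1.20e-10 (0.0526 estimated). The list median was 2.26, and 1.60 with genes at 0 counts held at their bound, and Cfi, a complement regulator, rose (5.34 ± 0.66). Of the 38 interferon response genes tested, 11 rose and 0 fell (15 and 1 in the list alone), with camera adjusted p = 0.00225 (0.641 estimated). Library medians were -0.003 in YSJZD replicate 1 and 0.74 and 0.811 in YSJZD replicates 2 and 3, and without YSJZD replicate 1 the number that rose was 17. They included Tap1 (1.99 ± 0.18), Gbp3 (2.34 ± 0.37) and Irf9 (0.82 ± 0.10). Ccl2 (4.96) moved over 1.5-fold without control replicate 3, as did Ccl2 (2.81) without YSJZD replicate 3. Rela lost its call in 3 of 9 leave-one-out fits (0.0879 without control replicate 2) and Nfkb1 lost its call in 7 of 9 leave-one-out fits (0.153 without YSJZD replicate 1).

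Of the 10 class II antigen presentation genes tested, 5 rose and 0 fell (5 and 0 in the list alone), with camera adjusted p = 0.00542 (0.262 estimated). They included H2-DMa (2.13 ± 0.19) and H2-DMb1 (1.96 ± 0.21), and Ciita stood at 8.49 ± 0.926 CPM against 2.52 ± 0.478 (1.75 ± 0.32). Of the 11 neutrophil markers tested, 5 rose and 0 fell (7 and 1 in the list alone), with camera adjusted p = 0.00325 (0.559 estimated). Over the fits without 1 library 2 (without control replicate 1 or YSJZD replicate 1) to 7 rose (without cisplatin replicate 1). The chemokine receptor Cxcr2 rose (2.35 ± 0.57), and S100a9 had a ratio of 31.6 with a 95% counting interval of 8.43 to 266. Of the macrophage and monocyte markers, 3 rose and 0 fell of 20 tested (4 and 0 in the list alone, camera adjusted p = 0.264), with Cd14 (5.05 ± 0.59) and Cd68 (1.82 ± 0.32) among them. Of the 14 endothelial markers tested, 0 rose and 5 fell (0 and 12 in the list alone), with camera adjusted p = 0.000174 (0.487 estimated). The VEGF receptor gene Kdr (-1.42 ± 0.34) and Emcn (-1.06 ± 0.27) fell. Over the fits without 1 library from 0 (control replicate 1 or YSJZD replicate 3 left out) to 12 endothelial markers fell, 12 without cisplatin replicate 3, where they stood apart, and with scaling by totals alone 1 did. Of the 82 ribosomal protein genes tested, 10 rose and 1 fell (6 and 1 in the list alone), with camera adjusted p = 9.16e-08 (0.641 estimated). Leaving out 1 library gave from 2 that rose (control replicate 2) to 18 (YSJZD replicate 2), and with scaling by totals alone 53 rose and 1 fell. Among the 10 that rose were Rps27l (0.99 ± 0.15), which is also in the p53 target list, and Rpl23 (0.75 ± 0.14). Cxcr2 lost its call without control replicate 1 (0.067) or YSJZD replicate 1 (0.0569), Kdr lost its call in 3 of 9 leave-one-out fits (0.0543 without control replicate 1) and Emcn lost its call in 5 of 9 leave-one-out fits (0.0853 without YSJZD replicate 1).

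Of the 32 NRF2 targets tested, 14 rose and 2 fell (15 and 4 in the list alone), with camera adjusted p = 0.00346 (0.608 estimated). Leaving out a control library or YSJZD replicate 1 gave 7 to 9 that rose. Gsta2 (2.92 ± 0.35), Nqo1 (1.70 ± 0.24) and Hmox1 (1.57 ± 0.30) rose. Of the 12 targets of the receptors AhR, CAR and PXR tested, 6 rose and 1 fell (6 and 1 in the list alone), with camera adjusted p = 0.0232 (0.151 estimated). The conjugating enzyme Ugt1a1 (3.35 ± 0.54) and the exporter Abcb1a (1.96 ± 0.33) rose. Among antioxidant enzymes, Sod1 (-0.62 ± 0.18), Sod2 (-0.84 ± 0.20), Cat (-0.54 ± 0.15) and Selenop (-1.33 ± 0.21) fell, and Gpx4 did not pass (0.14 ± 0.15, adjusted p = 0.552). Of the 18 heat shock genes tested, 2 rose and 8 fell (2 and 13 in the list alone), with camera adjusted p = 0.000471 (0.168 estimated). They included Hsph1 (-1.69 ± 0.20) and Dnaja1 (-1.51 ± 0.23). Of the 44 cell cycle genes tested, 0 rose and 1 fell (0 and 0 in the list alone), with camera adjusted p = 0.000236 (0.695 estimated). Without control replicate 1 the number that fell was 14, and without YSJZD replicate 3 it was 4. Cenpf fell (-1.93 ± 0.57), and the median of the list was -1.15 in control replicate 1 against 0.69 and 0.43 in the other control libraries. Ugt1a1 (2.75) moved over 1.5-fold without YSJZD replicate 2. Sod1 lost its call in 4 of 9 leave-one-out fits (0.13 without control replicate 1), Sod2 lost its call without control replicate 1 (0.061) or YSJZD replicate 1 (0.0551), Cat lost its call in 4 of 9 leave-one-out fits (0.114 without YSJZD replicate 3) and Cenpf lost its call in 6 of 9 leave-one-out fits (0.149 without control replicate 2).

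Of the 62 proximal tubule genes tested, 5 rose and 29 fell (5 and 30 in the list alone), with camera adjusted p = 2.29e-07 (0.17 estimated). Slc7a13 (-2.73 ± 0.31), the urea cycle enzyme Ass1 (-1.77 ± 0.21) and Slc22a2 (-0.86 ± 0.22) fell, and the transporters Slc13a1 (2.92 ± 0.28) and Slc6a18 (1.81 ± 0.18) rose. Slc13a1, a sulfate carrier, stood at 2147 ± 42.5 CPM with YSJZD, 314 ± 112 with cisplatin and 284 ± 66.4 in control. Of the 12 markers of the distal convoluted tubule tested, 0 rose and 5 fell (0 and 7 in the list alone), with camera adjusted p = 0.000787 (0.151 estimated). Leaving out a control library, YSJZD replicate 2 or YSJZD replicate 3 gave 3 that fell. Pvalb and the magnesium channel gene Trpm6 (-1.43 ± 0.21) fell, and Umod, a thick ascending limb gene, did not pass (-0.84 ± 0.40, adjusted p = 0.174). Of the 49 nuclear genes of the respiratory chain tested, 0 rose and 19 fell (0 and 25 in the list alone), with camera adjusted p = 2.51e-09 (0.524 estimated). Leaving out 1 library gave from 5 that fell (control replicate 1) to 20 (control replicate 3), with scaling by totals alone 10 fell, and examples were Ndufa10 (-0.70 ± 0.11) and Uqcrfs1 (-0.70 ± 0.14). Of the 22 genes of cholesterol and sterol synthesis tested, 1 rose and 9 fell (1 and 10 in the list alone), with camera adjusted p = 4.15e-05 (0.151 estimated). They included Cyp51 (-1.97 ± 0.24), Mvd (-1.38 ± 0.17) and Idi1 (-3.11 ± 0.46). Of the genes of fatty acid oxidation and PPARA, 18 rose and 9 fell of 51 tested (19 and 11 in the list alone, camera adjusted p = 0.0537), with Angptl4 (3.15 ± 0.20) and Acot1 (2.0 ± 0.16) higher. The copper transporter Slc31a1 fell (-0.66 ± 0.15). Slc22a2 lost its call in 4 of 9 leave-one-out fits (0.0752 without YSJZD replicate 3).

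Against control, 19 further lists did not pass, with camera adjusted p from 0.051 to 0.906. The numbers that rose and fell against control, with those in the list alone in brackets, were 6 and 5 of 27 ferroptosis and iron genes (7 and 5), 2 and 10 of 29 antioxidant enzymes (4 and 11), 2 and 3 of 13 oxidant-producing enzymes (2 and 3), 6 and 0 of 33 extracellular matrix genes (6 and 0), 10 and 11 of 32 unfolded protein response genes (11 and 12), 5 and 4 of 18 genes of cisplatin transport and metal binding (5 and 4) and 3 and 1 of 20 circadian clock genes (3 and 1). More were 2 and 3 of 20 hypoxia genes (2 and 4), 1 and 1 of 16 glycolysis genes (1 and 1), 1 and 3 of 8 gluconeogenesis genes (1 and 3), 1 and 4 of 13 fatty acid synthesis genes (2 and 5), 2 and 3 of 10 sex-linked and sex-biased genes (2 and 3), 2 and 4 of 13 thick ascending limb markers (2 and 4) and 0 and 0 of 11 principal cell markers (0 and 0). The final ones were 1 and 2 of 12 intercalated cell markers (1 and 2), 1 and 2 of 13 thin limb markers (1 and 2), 0 and 1 of 11 podocyte markers (0 and 0), 0 and 2 of 15 mesangial and fibroblast markers (0 and 1) and 1 and 0 of 5 T and NK cell markers (1 and 0). The median, mean and test direction differed in sign for the unfolded protein, cisplatin transport, hypoxia, sex-linked, intercalated cell and T and NK cell lists.

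The comparisons together ask how far YSJZD moved the genes that cisplatin had changed. Of the 7616 genes called in cisplatin against control, 4361 (57.3%) were called in the opposite direction in YSJZD against cisplatin, 2223 of 3987 that had risen and 2138 of 3629 that had fallen, and 23 were called in the same direction. In 15 simulated data sets with YSJZD equal to cisplatin at most 2 genes were called in the opposite direction. Of the 4361, 3077 did not pass against control, 1265 still did on the same side, and 19 were called on the other side. A further 1148 genes were not called between YSJZD and cisplatin and still differed from control. In all 2436 genes were called against control in the same direction in both cisplatin groups, while simulations, which share the control libraries in the same way, gave a mean of 0.2 with YSJZD equal to control and 6501.1 with YSJZD equal to cisplatin.

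These comparisons share libraries, which alone gives a covariance, and 15 simulated data sets with YSJZD equal to cisplatin measured it. In them 55.5% of the genes called against control had the opposite sign in YSJZD against cisplatin (54.7% to 56.2%), and in the data 95.3% did. The covariance of log2 fold changes across all genes was -1.51 in the data and -0.0605 in the simulations, and the correlation across genes, which are not independent replicates, was -0.84 against -0.10. The cisplatin group holds 3 libraries, so it could not be divided into parts of at least 2 libraries, and part of the excess may come from the shared libraries. The slope of YSJZD against control on cisplatin against control over the called genes was 0.46, where simulations gave 0.98 with YSJZD equal to cisplatin and 0.03 with YSJZD equal to control. Single YSJZD libraries gave slopes of 0.458, 0.327 and 0.375 (SD 0.0663) on log2 CPM with a prior count of 2, which shrinks changes, and on that scale cisplatin libraries gave 0.864 to 0.892.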

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

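The limma fit on log2(FPKM + 1) and the use of the fit without cisplatin replicate 3 were chosen only after the results were seen, and the other alternatives were planned. The counts of called genes kept within 1.5 times under the scaling, filter and fitting alternatives, from 6533 to 8023 in cisplatin against control, from 4184 to 5499 in YSJZD against cisplatin and from 2367 to 3348 in YSJZD against control, as did the count of reversed genes, from 3709 to 4799. The exception was the count with a change of at least 2-fold in YSJZD against cisplatin, which was 1698 in the limma fit on log2(FPKM + 1), where adding 1 shrinks changes of genes at low levels. With the replicate number as a block the counts were 7348, 4590 and 2367, the reversed genes numbered 4062 and the slope was 0.466. The replicate numbers do not pair the libraries, since the correlations of residuals between libraries of the same number lay between -0.197 and 0.092. With an estimated correlation camera called 0, 0 and 1 lists, and 13, 11 and 13 had unadjusted p under 0.05. Fry called 31, 27 and 21.

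Leaving out each library in turn gave 6576 to 7979 genes in cisplatin against control, 3496 to 4871 in YSJZD against cisplatin, 3184 to 4398 reversed genes and slopes of 0.423 to 0.498. In YSJZD against control the range was 1607 to 3138, with 1607 without control replicate 1 and 1699 without control replicate 2, and a group of 2 libraries has less power by construction. Among 107, 101 and 85 named values that passed, 107, 94 and 74 kept their call in every such fit. The fold of 10, 22 and 10 of these moved by more than 1.5 times when 1 library was left out. Of all named values limma on log2(FPKM + 1) moved 32, 29 and 26 folds as far, limma-voom moved Ccl6 (-3.911) and Hmga1b (-5.17) in YSJZD against cisplatin and Inmt (-5.705) in YSJZD against control, and the replicate block moved Ccl6 (-3.910) and Hmga1b (-6.299) in YSJZD against cisplatin. Under the scaling, filter and fitting alternatives 0, 4 and 7 of the calls were lost at least once. In YSJZD against cisplatin these were Hmga1b, Tnf (limma-voom, 0.0681), and in the fit of 6 libraries Havcr1 (0.0796), Nfkb1 (0.0533) and Tnf (0.0513). In YSJZD against control they were Slc34a1, Sod1 and Cat with totals alone (0.0668, 0.0736 and 0.0796), with the replicate block (0.0526, 0.0719 and 0.0583) and in limma on log2(FPKM + 1) (0.0617, 0.0794 and 0.0541), Cenpf in 5 alternatives (0.0516 to 0.214), Emcn with totals alone (0.0622), Cxcr2 in limma-voom (0.0595), and Nfkb1 in limma-voom (0.0683) and with DESeq2 size factors (0.0567). Emcn (0.072) and Cxcr2 (0.23) were also lost in limma on log2(FPKM + 1). Calls were also gained by values that had not passed. In YSJZD against cisplatin they were Cxcl1 without cisplatin replicate 1 (0.0144), and Umod without cisplatin replicate 3 (0.0203) or YSJZD replicate 1 (0.0449), in DESeq2 (0.024) and with the replicate block (0.0352). Gpx4 in cisplatin against control was called in DESeq2 (0.034). Some values that did not pass changed sign, and the cause was not tested. Bax in YSJZD against cisplatin lay from -0.27 to 0.105, above 0 without cisplatin replicate 2, YSJZD replicate 2 or YSJZD replicate 3. Hmox1 in the same comparison lay from -0.484 to 0.074, above 0 without cisplatin replicate 1. Bcl2 in YSJZD against control lay from -0.325 to 0.015, above 0 without YSJZD replicate 1, and was 0.018 with totals alone. Depth limits genes near the floor, such as Il6 and Tnf, and 3 libraries per group limit the calls of changes under 2-fold.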

Other observations

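The tests of long genes, of p53 targets and of cell types were chosen only after the results were seen, as were the counts of erythroid markers and the genes named here outside the rule, and the scaling test of the proximal tubule genes was planned. Haemoglobin transcripts were low in both cisplatin groups. Of 8 preset erythroid markers 4 were tested, and 4 fell with cisplatin and 3 with YSJZD against control. With YSJZD against cisplatin 2 rose, including Slc4a1, also an intercalated cell marker, but not Hba-a1. Hba-a1 stood at 373 ± 198 CPM in control, 1.07 ± 0.168 with cisplatin and 0.823 ± 0.256 with YSJZD, and Alas2, which starts haem synthesis in erythroid cells, at 8.5 ± 5.48, 0.019 ± 0.033 and 0.0979 ± 0.0894. The control libraries differed in their adult beta globin genes, with Hbb-bs at 190.1, 50.9 and 0 CPM and Hbb-b1, which belongs to another haplotype of that locus, at 0.146, 54.7 and 378 CPM in control replicates 1, 2 and 3, and no test was made of the genotype of these mice. The most abundant transcript in control was Kap, with 4.05% to 5.58% of counts, against 0.223% to 0.516% in cisplatin libraries and 0.996% to 2.18% in YSJZD libraries. Gene 105246811, without a symbol, took 0.728% to 2.19% of counts in cisplatin libraries and 0.004% to 0.136% in the others.

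Risen genes of fatty acid oxidation and PPARA did not return with YSJZD as matched genes did. Cyp4a10, a member, changed by 1.22 ± 0.21 with cisplatin against control, 1.51 ± 0.21 with YSJZD against cisplatin and 2.73 ± 0.22 with YSJZD against control. The 14 genes of fatty acid oxidation and PPARA that had risen had a median of 0.18 in YSJZD against cisplatin, against -0.76 in risen genes matched on rise and level (95% of sets from -1.14 to -0.51). The 16 risen NRF2 targets, of which 5 fell, had a median of -0.52 against -0.95 (-1.42 to -0.66). Of the 20 lists with at least 10 risen genes, 9 lay outside the 95% range of their matched sets. Above it were these 2 lists, the p53 targets and TNF signalling (-1.17 against -1.60), and those that returned further were the lists of cell cycle (-2.66 against -0.91), macrophage (-3.01 against -1.64), interferon (-1.89 against -1.46), extracellular matrix (-1.47 against -0.99) and ribosomal protein genes (-0.68 against -0.53). In YSJZD against control 239 genes were called that were not called in cisplatin against control, and 124 of them also passed in the same direction against cisplatin (77 higher, 47 lower), with Slc13a1 among the higher.

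Very long genes were lower in both cisplatin groups. Among 117 tested genes over 500 kb, 47.0% fell and 17.1% rose with cisplatin against control and 26.5% and 9.4% with YSJZD against control, while with cisplatin 24.8% fell and 33.2% rose among genes up to 10 kb, and 30 of the 117 fell in both comparisons with control, among them Wwox (-3.61 ± 0.40 and -3.5 ± 0.40, the latter -4.11 without YSJZD replicate 2) and Macrod2 (-4.12 ± 0.37 and -1.74 ± 0.33). Their median was -0.57 with cisplatin, and low expression or transcript length as the whole cause was argued against by random sets matched on CPM (one-sided permutation p = 0.0001, the smallest the draws can give) and on CPM with transcript length (matched median 0.11, permutation p = 0.0001). The median with YSJZD against control was -0.38 against -0.001 in matched sets, also with permutation p = 0.0001. In YSJZD against cisplatin 23.1% rose and 9.4% fell, and the median was 0.12 against -0.08 in matched sets (permutation p = 0.006). The lists hold 0.9% of these genes, so loss of the cell types that express them cannot be told apart from a change within cells. A candidate explanation is that platinum lesions, which block RNA polymerase, lower the output of a gene in step with its span, and no value here tests it against the loss of cells.

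The p53 targets that had risen with cisplatin fell less with YSJZD than matched risen genes. Their median was -0.54 against -1.15 in risen genes matched on rise and level (one-sided permutation p = 0.0002), which argues against the size of the rise and expression level as the cause. Without cisplatin replicate 3 the medians were -0.67 and -1.16 (permutation p = 0.0006), which argues against that library alone as the cause, and the other fits without 1 library gave permutation p from 0.0001 to 0.0002. Shares of called falls do not carry this contrast. Of the 34 targets 12 fell (35.3%), against 2223 of all 3987 risen genes (55.8%), but without cisplatin replicate 3 it was 18 of 34 (52.9%) against 56.9%, and without cisplatin replicate 2 it was 7 of 34 (20.6%) against 50.4%. If fewer immune cells with YSJZD were the cause, injury genes made by tubule cells may keep their rise too. The tubular injury genes outside the cell type lists gave permutation p = 0.782 and 10 epithelial genes among them gave permutation p = 0.356, which decides nothing, so fewer immune cells stays open beside DNA damage that lasts, which was not measured.

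The fall of proximal tubule genes with cisplatin had a median of -2.60. Scaling does not account for it, since the median was -2.37 with libraries scaled by totals alone. A loss of proximal tubule cells alone would raise the markers of other segments, and the highest median of the thick ascending limb list among cisplatin libraries was -1.63. Dilution by infiltrating cells would lower podocyte markers as far, and the podocyte median lay above the proximal tubule median by at least 2.09 in each cisplatin library. Loss of several tubule segments together and lower expression in the cells that remain may both contribute, and the bulk samples do not separate them.

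For each comparison 10 splits of the 6 libraries into groups of 3 can be made, and 10 splits cannot give a share under 0.05, the smallest being 0.1. The real split was the 1 split with as many genes in cisplatin against control (7616), in YSJZD against cisplatin (4942) and in YSJZD against control (2694), and the highest of the other splits was 0 in each. These counts are from edgeR, and at unadjusted p under 0.05 the real splits gave 8376, 6429 and 4584 genes and the highest of the others 678, 1234 and 816.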
